A study of Mus musculus with 48 samples.

How the data were processed

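Nascent RNA was sequenced from 8 libraries of the mouse embryonic stem cell line TCF2.2, 2 each with BRM014, DMSO, an shRNA against Chd4 and a scrambled shRNA. The deposited values are counts of reads per gene made by the authors for 55376 genes of mm10, with counts for 92 ERCC spike-in RNAs in the same libraries. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4, aligned with STAR 2.7.1a and counted with featureCounts, and edgeR 3.32.1 was used after that. The notes do not say which strand was counted or how reads with several alignments were treated. All 37 mitochondrial genes had 0 counts. The 40 chromatin immunoprecipitation samples were not analysed here. Gene symbols were kept as given. Of these, 54512 occur in a table of gene names and 38407 in a RefSeq table, 0 are duplicated, and 1336 genes have no coordinates.

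Groups were taken from the sample labels. The sample titles number the libraries of each group 1 and 2, while the columns r4 (Chd4 shRNA) and r3 (scrambled) match no title and were placed by their group name. Before the data were examined, the comparisons, the test, the gene lists, the rule for named genes and most of the other settings were fixed. The comparisons were BRM014 against DMSO, Chd4 shRNA against scrambled shRNA, and the difference between both effects. The 8 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test, on the 35426 genes that passed its default filter on low counts. Library sizes came from the ERCC totals after TMM scaling among all 92 ERCC RNAs, since these were added per cell number. Of the 92, 86 had few counts, between 68 and 375 in total per library, from a source that is not known. Including them changed the sizes, as given below, so this scale is an uncertain measure per cell. The other scaling fixed then was TMM scaling of the gene counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and SEs were taken from the F statistic. The libraries labelled with replicate numbers were not treated as pairs in the test. With 2 libraries against 2, an exact permutation test of a single value cannot go below 0.333.

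A further fit was added after the data were seen. It used the 8017 genes whose mean count over the 8 libraries was at least 10-fold above the mean background, with TMM scaling of those genes. Background was measured on 1434 olfactory and vomeronasal receptor genes, as counts per kb over 5330.3 kb of exon. Gene and list values are given from this fit, so they are relative to other expressed genes.

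The genes named were Chd4, Smarca4 and Smarca2, then the 10 largest rises and the 10 largest falls among called genes with an average abundance above the median tested gene and with both treated libraries on the same side of both controls. Genes without a symbol or with only a predicted or clone name were left out. For each gene list described, up to 4 members with the smallest p were named, and for the difference the 5 smallest p in each direction. Other genes are given as chosen after their values were seen. The 36 lists were written from general knowledge. Those with at least 3 members in a fit were tested against the other genes with camera of limma 3.58.1, in 105 tests over all tested genes and 69 over expressed genes, at a preset correlation of 0.01, then again with an estimated correlation. Their p were adjusted over all lists tested and the 3 comparisons.

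The alternatives were DESeq2 1.42.0 with ERCC or gene size factors, plain ERCC sums as library sizes, no filter on low counts, at least 50 counts in at least 2 libraries, an absolute log2 fold change of at least 1, the replicate number as a block, each comparison on its own 4 libraries, and each library left out in turn. Those added after the data were seen were TMM over the 6 abundant ERCC RNAs, a robust fit, a filter on TMM-scaled gene library sizes, the expressed genes, those genes at 3-fold and 30-fold above background, and a subtraction of the background in proportion to exonic length. Figures were drawn with matplotlib 3.10.9.

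The fits were tested on simulated data with 2 libraries in each group. Among expressed genes, 48 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered in the BRM014 comparison, with 13 unchanged genes called. In the Chd4 shRNA comparison 36 of 67, 53 of 67 and 64 of 66 were recovered, with 5 unchanged genes called. On all tested genes with the ERCC scale, none of the 1.5-fold and 2-fold changes were recovered in either comparison, and 5 of 66 and 8 of 66 of the 4-fold changes were. Of 30 simulated lists without a change, 0 were called by camera. The simulated genes varied independently of each other, so this cannot show how often camera calls lists whose genes vary together. The library sizes used to simulate the counts were also used to fit them, and every group had the same background. Recovery and false calls thus leave out errors of scaling and the higher background of the libraries labelled Chd4 shRNA.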

Results

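Nascent RNA was measured in 8 libraries of TCF2.2, a mouse embryonic stem cell line kept in 2i medium. Cells took up 500 µM 4-thiouridine for 5 min, and the RNA made in that time was pulled down through its label and sequenced. There were 4 groups of 2 libraries: cells given BRM014 at 10 µM, an inhibitor of the SWI/SNF ATPases BRG1 and BRM, for 3 h, cells given DMSO for 3 h, cells with a lentiviral shRNA against Chd4, the ATPase of NuRD, and cells with a scrambled shRNA, both at 24 h in 1.5 µg/mL puromycin. Total gene counts were 12977098 and 14582377 in the BRM014 libraries r1 and r2 and 17128981 and 16813866 in the DMSO libraries r1 and r2. They were 7461362 and 6982354 in the libraries labelled Chd4 shRNA (r1 and r4) and 12026026 and 11298835 in the scrambled libraries (r1 and r3). The series also lists 40 chromatin immunoprecipitation samples of Pol II phosphorylated at serine 5 or serine 2, of H2A.Z and of H3.3, which were not analysed here. Its title asks how changes in expression after loss of SWI/SNF or NuRD go with Pol II at promoters, and the nascent RNA gives the expression side of that question.

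The ERCC RNAs, synthetic RNAs added to the lysate in proportion to the number of cells, were used to scale nascent RNA per cell. Whether they carried the label that was pulled down is not stated, so the ratios are given as counts per ERCC count. Gene counts per ERCC count were 100.2 ± 11.3 (SD, n = 2) with BRM014 and 108 ± 7.69 (SD, n = 2) with DMSO, a log2 ratio of -0.11 (0.07 with TMM-scaled ERCC totals and 0.16 with the ERCC size factors of DESeq2). They were 259 ± 70.7 (SD, n = 2) with the libraries labelled Chd4 shRNA and 193 ± 0.345 (SD, n = 2) with the scrambled shRNA, a log2 ratio of 0.43 (0.0096 and -0.18 with the same alternatives). The value of 0.0096 rested partly on the 86 ERCC RNAs with few counts. TMM over all 92 set Chd4 shRNA r1 and r4 and scrambled r1 and r3 at relative sizes of 0.606, 0.506, 0.926 and 0.873. TMM over the 6 abundant ones set them at 0.511, 0.301, 0.754 and 0.741, nearer to the plain sums (0.456, 0.289, 0.797 and 0.751). No ratio was computed with the 6 alone. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, and no other test of these ratios was run. The 1434 olfactory and vomeronasal receptor genes, which stem cells do not need, had 6.99 ± 0.303 counts per kb of exon (SD, n = 2) in the libraries labelled Chd4 shRNA against 1.58 ± 0.361 in the scrambled, 2.15 ± 0.696 in the BRM014 and 2.65 ± 0.0208 in the DMSO libraries. Their level is called background below, although it may come from stray reads or from transcription of silent genes. Scaled to all exons, it came to 11.9% and 13.6% of the gene counts of the libraries labelled Chd4 shRNA and to between 1.45% and 2.38% in the other 6. Some abundant gene rows were taken as ribosomal RNA sequence, among them that of the protein-coding gene Lars2. They took 37.5% ± 1.82 of the counts with the libraries labelled Chd4 shRNA and 57.8% ± 2.44 with the scrambled shRNA. With BRM014 they took 40.7% ± 9.24 and with DMSO 44.7% ± 1.40 (SD, n = 2 each).

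**Figure D1:**
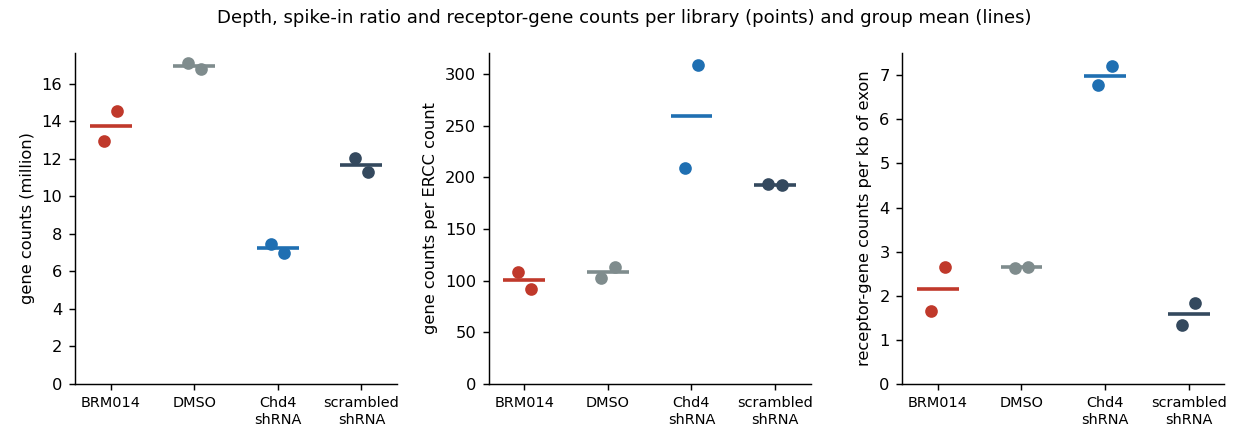
Total gene counts, gene counts per ERCC count and receptor-gene counts per kb of exon, for each of the 8 libraries (points) with the group mean (lines). Both libraries labelled Chd4 shRNA lie above all the others in receptor-gene counts, at a mean of 6.99 per kb against 1.58 with the scrambled shRNA.

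Because of this background, genes and gene groups are described below from 8017 genes, each relative to the other expressed genes. Their mean count over the 8 libraries was at least 10-fold above the mean background. In the libraries labelled Chd4 shRNA alone some lay closer to it, such as Tfap2c, with 52 and 60 counts where background alone would give 25.7. The set of 8017 genes was chosen after the data were seen, and the counts over all 35426 tested genes stand beside it. On the ERCC scale the median of the expressed genes itself shifted by 0.14 (log2) with BRM014 and by 0.18 in the libraries labelled Chd4 shRNA, and by 0.004 and 0.59 where the plain ERCC sums set the scale. Scaled by all tested genes, background included, it shifted by 0.06 and -1.34. A value called higher or lower in the following paragraphs is therefore a change against the typical expressed gene.

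The first comparison asked which genes changed their transcription after 3 h of SWI/SNF inhibition. BRM014 raised Insig1, which restrains sterol synthesis (chromosome 5, 28071363 to 28078662, mm10), 3.07-fold, at a log2 fold change of 1.62 ± 0.14 (SE, n = 2 against 2, adjusted p 2.69e-07). It raised Ddit3, a stress-induced transcription factor (chromosome 10, 127290774 to 127296288), 2.43-fold (1.28 ± 0.12, adjusted p 9.4e-07), and Bhlhe40, a transcriptional repressor, 2.55-fold (1.35 ± 0.16). Fgf4, the growth factor that stem cells secrete (chromosome 7, 144847367 to 144865243), fell to 0.292 of its DMSO level (-1.78 ± 0.14, adjusted p 7.69e-08), and the Y RNAs Rny1 and Rny3, made by Pol III, fell with log2 fold changes of -2.31 ± 0.22 and -1.53 ± 0.18. The 10 genes with the largest rise by the rule for named genes, which sets a minimum abundance, also included Gdap10 (2.07 ± 0.19), Slc20a1, a phosphate transporter (1.12 ± 0.14), Ptp4a1, Nampt of NAD salvage, Tmem41b, Pip4p1 and the translation factor Eif5, the last 5 at 0.88 to 1.00. The 10 with the largest fall by that rule also included Gfod2 (-1.63 ± 0.15), Snord118 (-1.52 ± 0.15), n-R5-8s1 of 5.8S ribosomal RNA (-1.45 ± 0.26, not called by DESeq2 or a robust fit), n-R5s193 of 5S ribosomal RNA (-1.38 ± 0.16), Snord49b (-1.37 ± 0.23) and Dqx1 (-1.31 ± 0.22). Nlrp12 (-1.67 ± 0.13) overlaps the microRNA genes Mir291a to Mir295, which lie on the opposite strand except Mir292b, so its counts may not be its own. Mir290a, named outside the rule after its values were seen, fell by 2.11 ± 0.18. The genes encoding the inhibitor's targets gave 0.11 ± 0.16 for Smarca4 (BRG1, chromosome 9, 21616169 to 21704230; adjusted p 0.757), while Smarca2 (BRM) had 41 and 42 counts with BRM014 against 66 and 56 with DMSO, too few for the expressed set.

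Of the 8017 expressed genes, 197 were higher and 376 lower with BRM014 at an adjusted p under 0.05 (edgeR), 16 and 120 of them with an absolute log2 fold change of at least 1. The 550 expressed genes of at most 200 bases held 5 of those higher and 166 of those lower. For these short genes a loss of short fragments is left open below. Over all 35426 genes on the ERCC scale, 0 were higher and 2 lower, namely Gm48188 (-4.33 ± 0.88, adjusted p 0.0136, 0 and 2 counts with BRM014 against 23 and 31 with DMSO) and Gm26917, a row of ribosomal RNA sequence (-1.31 ± 0.24, adjusted p 0.00186). Both lie outside the rule for named genes and were named after their values were seen. At an unadjusted p under 0.05 edgeR had 236 higher and 368 lower there, and DESeq2 with ERCC size factors called 9 and 6. Over the same genes with gene-based scaling, edgeR called 416 higher and 568 lower. The ERCC-scaled counts rested on single DMSO libraries, with 8456 genes higher without DMSO r2 and 1036 lower without DMSO r1. The ERCC scale set the DMSO libraries r1 and r2 at relative sizes of 2.36 and 1.14, although their ERCC totals were 167318 and 148472. TMM over the 6 abundant ERCC RNAs set them at 2.12 and 1.87. The wider gap thus came from including the other 86, which had 172 and 150 counts there. Among expressed genes the count of higher genes was 85 without BRM014 r1, 91 without BRM014 r2 and 762 without DMSO r2, and that of lower genes 235, 148 and 671.

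With BRM014, camera called 3 lists of genes with a shared function at its preset correlation and 0 with an estimated correlation. Of 14 expressed genes of the integrated stress and unfolded protein responses, 4 rose and 0 fell, the same adjusted over the list alone: Ddit3, Herpud1 of protein degradation at the endoplasmic reticulum (0.79 ± 0.13), the chaperone gene Hspa5 (0.85 ± 0.14) and the stress regulator Atf4 (0.51 ± 0.13). The call for Atf4 ended without BRM014 r1 (adjusted p 0.0953), BRM014 r2 (0.196) or DMSO r1 (0.0763), and on the 4 libraries alone (0.0767). Their list median was 0.14, with a camera adjusted p of 0.00366 (0.0521 without DMSO r1), and the adjusted p was 0.875 with an estimated correlation. Of 13 noncoding RNAs of Pol I, Pol III, the spliceosome and the nucleus, 6 fell, or 7 adjusted over the list alone, and 0 rose: Vaultrc5 (-1.69 ± 0.21), Neat1 (-1.11 ± 0.15), Malat1 (-0.81 ± 0.18, adjusted p 0.0949 without BRM014 r2 and 0.0556 at 30-fold above background) and the spliceosomal RNAs Rnu11 (-0.99 ± 0.14), Rnu12 (-0.94 ± 0.15) and Rnu1b1 (-0.79 ± 0.13). The list median was -0.52 (camera adjusted p 1.83e-05; adjusted p 0.875 with an estimated correlation). Of 66 replication-dependent histone genes 5 fell, or 8 adjusted over the list alone, with Hist2h4 at -0.95 ± 0.16 and Hist1h1b at -0.61 ± 0.16 (adjusted p 0.409 without BRM014 r2, 0.145 without DMSO r1 and 0.0832 at 30-fold above background), and a median of -0.32. Their camera adjusted p of 1.7e-05 became 0.972 with an estimated correlation, 0.0853 without BRM014 r2 and 0.343 without DMSO r1. The count of lower histone genes was 3 by DESeq2, 4 with the background subtracted, 1 scaled by all tested genes and 0 with plain ERCC sums, where 1 stress gene was higher and 2 noncoding RNAs lower.

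Among 16 expressed genes of naive pluripotency, Fgf4, Klf4 (-0.65 ± 0.14, adjusted p 0.00471, but 0.162 without BRM014 r2) and the nuclear receptor gene Nr0b1 (-0.50 ± 0.13, adjusted p 0.019, but 0.162 without BRM014 r1, 0.196 without BRM014 r2 and 0.135 by DESeq2) fell with BRM014 and 0 rose, with 5 lower adjusted over the list alone. The median was -0.08 (0.01 with TMM-scaled ERCC totals), and the camera adjusted p of 0.0719 missed the threshold, though it was 0.00433 without DMSO r1 and 0.0391 without BRM014 r1. Of 9 general pluripotency genes, Utf1 fell (-0.68 ± 0.13, adjusted p 0.167 without BRM014 r2), with 2 lower adjusted over the list alone, while Pou5f1, which encodes OCT4, was at -0.09 ± 0.13. Zfp296, a zinc finger gene of stem cells, fell by 1.61 ± 0.18, among 2 higher and 3 lower of 78 Zfp genes. Of 7 immediate early genes Klf6 (1.08 ± 0.14) and Klf10 (0.71 ± 0.14) rose, or 3 adjusted over the list alone, where 1 fell. That list's median (-0.06, but 0.09 with TMM-scaled ERCC totals) and mean (0.18) differed in sign, and its camera adjusted p was 0.428. Of 17 genes of Pol II pausing and elongation, 13 of G1/S and 88 ribosomal protein genes, edgeR called 0 higher and 0 lower, as it did for 11 NuRD genes, of which 1 was higher adjusted over the list alone. Of 14 SWI/SNF subunit genes 1 fell, Bcl7b (-0.52 ± 0.15, adjusted p 0.0299). That call ended by DESeq2 (0.211), scaled by all tested genes (0.0729) and without BRM014 r1 (0.143), BRM014 r2 (0.301) or DMSO r1 (0.131), and with either ERCC scaling. Of 15 p53 targets the cyclin gene Ccng1 rose (0.52 ± 0.13, adjusted p 0.0951 without BRM014 r1, 0.115 without BRM014 r2 and 0.0625 without DMSO r1), with 4 higher and 2 lower adjusted over the list alone. Of 10 genes for H2A.Z and H3.3 and their handling Ep400 fell (-0.69 ± 0.15, adjusted p 0.0803 without BRM014 r2).

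**Figure D2:**
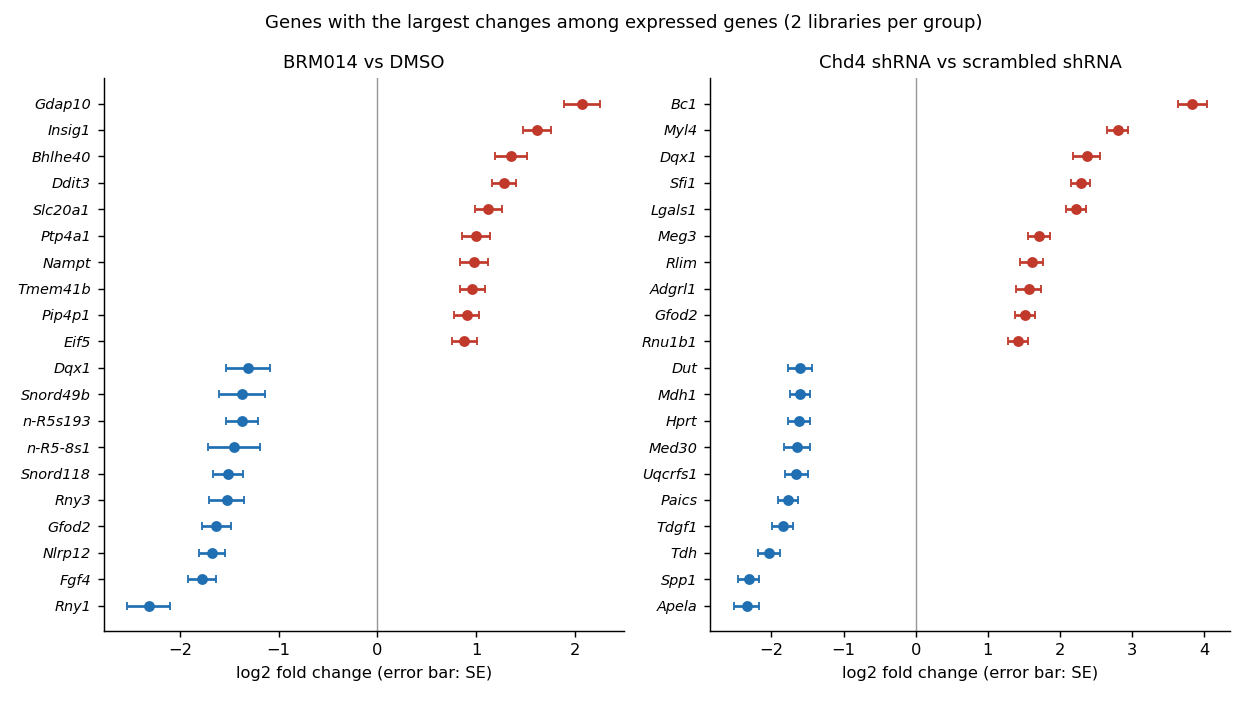
Log2 fold change with its SE for the 10 genes with the largest rise and the 10 with the largest fall among 8017 expressed genes, as picked by the rule for named genes in the BRM014 and in the Chd4 shRNA comparison, each of 2 libraries against 2. The values shown run from -2.31 (Rny1) to 2.07 (Gdap10) with BRM014 and from -2.35 (Apela) to 3.83 (Bc1) in the libraries labelled Chd4 shRNA.

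The second comparison asked which genes changed their transcription after knockdown of Chd4. Chd4 itself (chromosome 6, 125095981 to 125130591) had 730 and 760 counts in the libraries labelled Chd4 shRNA (r1 and r4), 806 and 618 in the scrambled (r1 and r3), 772 and 900 in the BRM014 and 726 and 1059 in the DMSO libraries. On the ERCC scale its log2 fold change in the libraries labelled Chd4 shRNA was 0.78 ± 0.52 (SE, n = 2 against 2, adjusted p 0.189). Against the other expressed genes it was 0.59 ± 0.16 (adjusted p 0.00614), but 0.40 ± 0.18 (adjusted p 0.114) without scrambled r3, and 0.22 and not called among genes at least 3-fold above background. Scaled by all tested genes, background included, it was -0.76. A lower Chd4 count was thus seen only under scalings that include the background. These counts are of RNA made within 5 min, not of the stock of Chd4 RNA or protein. They therefore cannot show whether the knockdown worked, and the following values describe the libraries by their label.

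Some genes of the pluripotent state were among those lower in the libraries labelled Chd4 shRNA. Nr0b1 fell to 0.191 of its scrambled level, at a log2 fold change of -2.39 ± 0.18 (SE, n = 2 against 2, adjusted p 3.84e-09), and Nanog, a core regulator of naive pluripotency, to 0.343 (-1.54 ± 0.15, adjusted p 1.03e-07). Tdgf1, a Nodal co-receptor gene, fell by 1.85 ± 0.14, Fgf4 by 1.42 ± 0.15, Pou5f1 by 1.04 ± 0.13 and Sox2 by 1.02 ± 0.19. The genes with the largest rise were Bc1, a small RNA of Pol III (chromosome 7, 144914470 to 144914637), 14.3-fold higher (3.83 ± 0.20, adjusted p 4.43e-11), and the myosin light chain gene Myl4, 6.95-fold higher (2.80 ± 0.15). Crabp2, which encodes a retinoic acid binding protein, was 13.1-fold higher (3.71 ± 0.18) but lies outside the rule for named genes and was named after its values were seen. The other large rises by the rule were Dqx1 (2.37 ± 0.19), Sfi1 (2.29 ± 0.13), Lgals1 of galectin 1 (2.22 ± 0.14), the imprinted noncoding gene Meg3 (1.71 ± 0.15), Rlim, an E3 ligase of X inactivation (1.61 ± 0.16), Adgrl1 (1.56 ± 0.17), Gfod2 (1.51 ± 0.14) and the U1 RNA gene Rnu1b1 (1.42 ± 0.14). The other large falls by the rule were Apela, a peptide hormone gene (-2.35 ± 0.18), Spp1 of osteopontin (-2.32 ± 0.15), the threonine dehydrogenase gene Tdh (-2.04 ± 0.15), Paics of purine synthesis (-1.77 ± 0.14), Uqcrfs1 of respiratory complex III (-1.66 ± 0.16), Med30 of Mediator (-1.64 ± 0.18), Hprt of purine salvage (-1.62 ± 0.15), Mdh1 (-1.61 ± 0.14) and Dut (-1.60 ± 0.17). Sfi1 overlaps Drg1 on the same strand (mean counts 873 and 694), so part of its counts may belong to that gene. Among the genes named for BRM014, Snord49b lies in a gene of the same strand with a mean count of 4761 against its own 574. The gene n-R5s193 overlaps a row of the same strand with nearly the same mean count (523.62 against 523.75).

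Of the 8017 expressed genes 1634 were higher and 1621 lower in the libraries labelled Chd4 shRNA (edgeR), 317 and 259 of them with an absolute log2 fold change of at least 1. With the background subtracted, 3332 were called against 3255, with 2748 in common. The higher count was 1079 without Chd4 shRNA r4 and 1064 without scrambled r3, and the lower count 1046 without Chd4 shRNA r1. Over all 35426 tested genes on the ERCC scale, 21666 were higher and 68 lower, with a median log2 fold change of 1.93, and gene-based scaling gave 11493 and 11134. The 10 largest rises by the rule there were of genes with 38 to 68 counts in each library labelled Chd4 shRNA. They included Vmn1r198 (4.73 ± 0.75) and the pancreatic elastase gene Cela2a (4.65 ± 0.71). Vmn1r198 had 47 and 38 counts where background alone would give 43.765, so its rise was at the level of background. Cela2a, with 68 and 58 counts against 12.048, lay above it. The median expressed gene lay at only 0.18 on the ERCC scale. How many of the 21666 rises were background was not tested. The higher count was 13247 without Chd4 shRNA r4, and the lower count ranged from 8 without Chd4 shRNA r1 to 636 without DMSO r1.

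By list, 10 of 16 naive pluripotency genes fell, or 12 adjusted over the list alone, and Stat3 rose (0.71 ± 0.15, but 0.34 and not called at 3-fold above background, adjusted p 0.0561). Their median was -0.65 and the camera adjusted p 0.000157 (0.875 with an estimated correlation). With plain ERCC sums the median was -0.08, with 3 lower and 1 higher. Of 9 general pluripotency genes 6 fell and 2 rose, with the same counts adjusted over the list alone, and Trim28 was at -0.97 ± 0.14 (median -0.87, camera adjusted p 0.0324, or 0.875 with an estimated correlation). With plain ERCC sums the median was -0.28, with 1 lower and 2 higher. The camera call ended with the background subtracted (0.0777) and without scrambled r1 (0.0543). Of 7 targets of LIF and STAT3, 4 of them also in the naive list, 4 fell, or 5 adjusted over the list alone, and 1 rose (Stat3), with Pim3 at -1.41 ± 0.16 and Socs3 at -1.26 ± 0.16 (camera adjusted p 0.0366, 0.0683 without scrambled r1 and 0.875 with an estimated correlation). Their median was -0.53, but 0.07 where plain ERCC sums set the scale and -0.85, with 5 lower, with the background subtracted. Of 13 genes of G1/S, 10 fell and 0 rose, also adjusted over the list alone, among them Pcna, the sliding clamp of replication (-1.45 ± 0.14), Rrm2 (-1.19 ± 0.16), Ccnd3 (-1.02 ± 0.14) and Mcm5 (-0.83 ± 0.13), with a median of -0.81 and a camera adjusted p of 4.59e-05 (0.875 with an estimated correlation). With plain ERCC sums the median was -0.18, with 1 lower. Of 66 replication-dependent histone genes 24 fell, as with Hist1h1c (-1.07 ± 0.18), and 4 rose, with the same counts adjusted over the list alone. Their median was -0.35 (0.20 with plain ERCC sums) and the camera adjusted p 0.00251, or 0.999 with an estimated correlation, 0.225 with the background subtracted (median -0.14, 18 lower) and 0.456 without Chd4 shRNA r4. Of 12 housekeeping genes 6 fell, or 7 adjusted over the list alone, and 0 rose, with the glycolysis gene Pgk1 at -0.81 ± 0.13. Their median was -0.35 (0.25 with plain ERCC sums) and the camera adjusted p 0.0185, or 0.875 with an estimated correlation and 0.166 with the background subtracted (median -0.18, 4 lower).

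Of 17 genes of Pol II pausing and elongation 9 rose, or 10 adjusted over the list alone, and 0 fell in the libraries labelled Chd4 shRNA. They included Aff4 (1.15 ± 0.16) and Ell (0.92 ± 0.15) of the super elongation complex, and the elongation factor gene Supt6 (1.14 ± 0.15). The list median was 0.40, but -0.95 when scaled by all tested genes, and the camera adjusted p 0.0336 (0.0632 without scrambled r3 and 0.875 with an estimated correlation). Of 78 Zfp genes 28 rose, as with Zfp866 (1.15 ± 0.16), and 7 fell, among them the pluripotency gene Zfp42 (-1.05 ± 0.13), with the same counts adjusted over the list alone. Their median was 0.31 (-1.04 scaled by all tested genes) and the camera adjusted p 0.00404 (0.875 with an estimated correlation). Of 13 noncoding RNAs 4 rose and 0 fell, also adjusted over the list alone, among them Neat1 (1.36 ± 0.15) and Malat1 (1.09 ± 0.18), with a median of 0.35 (negative when scaled by all tested genes). With the background subtracted 8 rose, with a median of 0.56, and 6 did by DESeq2. Their camera adjusted p was 0.0331, or 0.875 with an estimated correlation, 0.112 without Chd4 shRNA r1 and 0.0627 without scrambled r3. None of the 9 lists called in this comparison held with an estimated correlation.

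Other lists split or missed the threshold. Of 14 genes of the integrated stress and unfolded protein responses 4 rose, among them Hspa5 (1.18 ± 0.15), Ddit3 (0.99 ± 0.14) and Herpud1 (0.95 ± 0.15), and 4 fell, among them Asns (-1.24 ± 0.14) and Atf4 (-0.66 ± 0.14). Of 16 genes of G2/M 6 rose, including the kinetochore genes Cenpe (1.19 ± 0.14) and Cenpf (1.19 ± 0.15), and 6 fell, including Cdk1 (-0.87 ± 0.13), and the list's median (-0.12) and mean (0.08) differed in sign. That split depended on the scaling, with 7 higher and 0 lower with plain ERCC sums, and 0 and 14 when scaled by all tested genes. Under those scalings the stress genes gave 4 and 0, and 0 and 13, and the Pol II subunit genes below 6 and 0, and 0 and 12. Of 11 NuRD genes 2 rose and 5 fell, or 6 adjusted over the list alone, with the deacetylase gene Hdac2 at -1.12 ± 0.15 and a median of -0.33 (0.26 with plain ERCC sums). Of 14 SWI/SNF genes 7 rose, with Arid1a at 0.90 ± 0.15 and Smarca4 at 0.61 ± 0.17 (adjusted p 0.00672, but 0.13 without scrambled r3 and 0.207 at 3-fold above background), and 1 fell, Actl6a (-0.97 ± 0.14). Their median of 0.31 was -1.04 when scaled by all tested genes. Smarca2 had 126 and 148 counts in the libraries labelled Chd4 shRNA and 36 and 44 in the scrambled, where the level at receptor genes, scaled to its exons, would alone give 99.8 and 22.5. Of 10 genes for H2A.Z and H3.3 and their handling 4 rose, among them H3f3b (0.81 ± 0.14), and 2 fell, among them H2afz (-0.99 ± 0.15). With plain ERCC sums 5 of them rose and 0 fell, and scaled by all tested genes 0 rose and 10 fell. Of 13 Pol II subunit genes 5 rose, with Polr2a at 1.07 ± 0.16, and 5 fell, and the median (-0.03) and mean (0.11) differed in sign. Of 7 immediate early genes 3 fell, or 4 adjusted over the list alone, with Ier2 at -1.25 ± 0.14 (median -0.48, camera adjusted p 0.0719). The median was 0.08 with plain ERCC sums and -0.85, with 5 lower, with the background subtracted. Marker lists of other cell types had few expressed members. Of 4 trophectoderm markers Krt18 rose (1.65 ± 0.19) and Tfap2c fell (-0.67 ± 0.18, adjusted p 0.0895 without Chd4 shRNA r1 and 0.133 without scrambled r3). Of 1 to 2 expressed markers each of primitive endoderm, neural cells, fibroblasts and the germline, Vim (-0.76 ± 0.16) and Hormad1 (-1.07 ± 0.21) fell and Lamc1 rose (0.41 ± 0.15, adjusted p 0.0315). The call for Lamc1 ended without Chd4 shRNA r1 (0.0549), Chd4 shRNA r4 (0.218) or scrambled r3 (0.302) and at 3-fold above background (0.855). With BRM014 the neural marker Tubb3 fell (-0.66 ± 0.16, adjusted p 0.0133, but 0.0602 by DESeq2, 0.337 without BRM014 r2 and 0.0561 without DMSO r1). Each rise of a list or gene given here for the libraries labelled Chd4 shRNA is against other expressed genes, and 17 named rises turned negative when scaled by all tested genes.

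**Figure D3:**
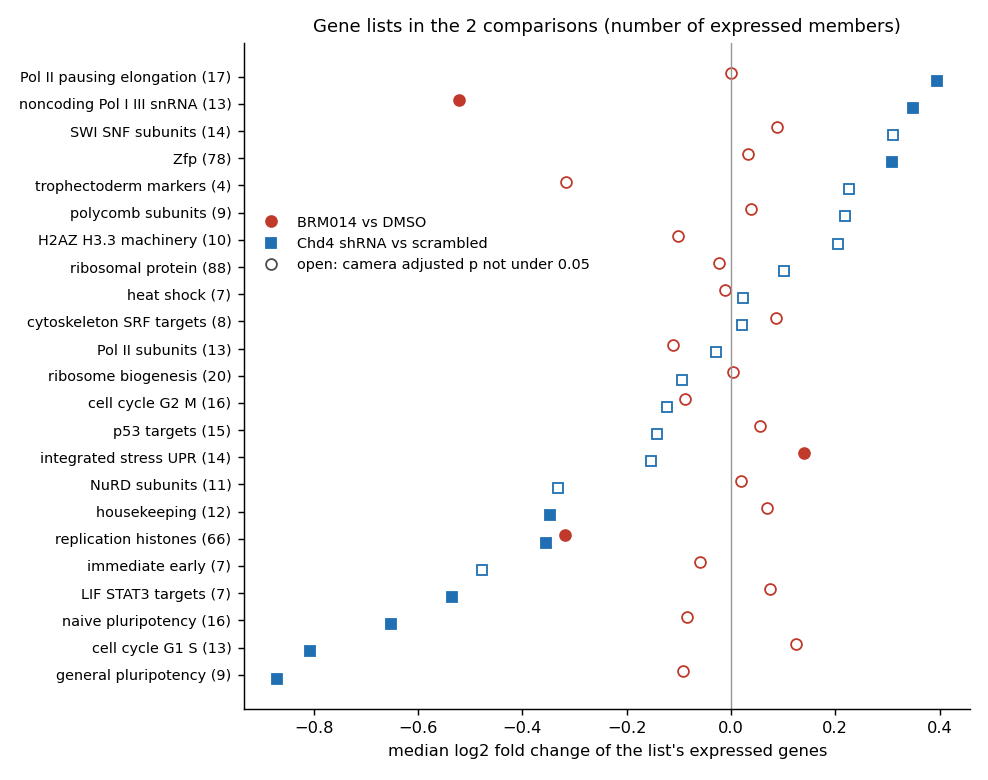
Median log2 fold change of the expressed members of each gene list with at least 3 of them, with their number in brackets, in the BRM014 comparison (circles) and the Chd4 shRNA comparison (squares). Filled symbols mark a camera adjusted p under 0.05 at the preset correlation, which none of the lists kept with an estimated correlation, and the medians shown run from -0.87 to 0.40 in the libraries labelled Chd4 shRNA, where several change sign with the scaling.

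The third comparison set the effects of BRM014 and of the Chd4 shRNA against each other, each against its own controls. Insig1 rose with BRM014 and fell in the libraries labelled Chd4 shRNA (-0.68 ± 0.15), a difference of 2.30 ± 0.21 (log2 ± SE, n = 2 libraries in each of 4 groups, adjusted p 9.07e-08). Pim3, a kinase gene downstream of LIF, likewise rose (0.62 ± 0.12, adjusted p 0.0501 without BRM014 r1) and fell, a difference of 2.03 ± 0.20. Gfod2 and Dqx1 moved the opposite way, down with BRM014 and up in the libraries labelled Chd4 shRNA, with differences of -3.15 ± 0.20 and -3.68 ± 0.29. Spp1 (2.52 ± 0.20), Apela (2.64 ± 0.22) and Paics (2.02 ± 0.19) differed after a fall in the libraries labelled Chd4 shRNA alone, and Bc1 (-4.42 ± 0.27), Sfi1 (-2.40 ± 0.18) and Myl4 (-2.87 ± 0.23) after a rise there alone. Nanog differed by 1.17 ± 0.20 (adjusted p 0.000199). For Fgf4, lower in both, the difference of -0.36 ± 0.20 did not pass (adjusted p 0.182), nor did that of 0.30 ± 0.19 for Ddit3, higher in both (adjusted p 0.244). Both depended on the setting: that of Fgf4 passed without DMSO r1 (-0.50, adjusted p 0.0302) and was 0.05 at 3-fold above background, where that of Ddit3 passed (0.70, adjusted p 0.00539). Scaled by all tested genes both passed, at 1.07 and 1.72.

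Among expressed genes 2473 differed between both effects, 1161 with a more positive change with BRM014 and 1312 with a more negative one. Of these, 1974 were called in the Chd4 shRNA comparison alone, 161 in the BRM014 comparison alone, 118 in both with opposite signs, 20 in both with the same sign and 200 in neither. The number was 1611 without Chd4 shRNA r1. Over all tested genes on the ERCC scale 12650 differed, a count that ranged from 1591 without BRM014 r2 to 24313 without DMSO r1, and gene-based scaling gave 9721 and 6569. Genes lower in both comparisons numbered 97 where 76.0 were expected from the group sizes (Fisher's exact test, two-sided, p 0.00696, Benjamini-Hochberg adjusted 0.0139 over 12 tables). Genes higher in both numbered 46 against 40.2 expected (adjusted p 0.426), those higher with BRM014 and lower in the libraries labelled Chd4 shRNA 36 against 39.8 (adjusted p 0.636), and the reverse 82 against 76.6 (adjusted p 0.628). Fisher's test takes genes as independent, which they are not. Both sets of calls also came from the same fit with shared estimates of spread, which may by itself raise their overlap. The overlap counts changed with the set of genes and the scaling, which were varied together. With gene-based scaling of all tested genes, 305 were lower in both against 179 expected (adjusted p 6e-28) and 9 higher in both against 135 (5.36e-56). Those higher with BRM014 and lower in the libraries labelled Chd4 shRNA numbered 328 against 131 (4.19e-88), and the reverse 31 against 184 (5.36e-56). On that scale, background included, the median expressed gene itself lay at -1.34 in the Chd4 shRNA comparison. The typical expressed gene was thus lower there whatever its change with BRM014, so these overlaps cannot show shared or opposed effects. Across the 8017 genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.07 and a Spearman rho of -0.08, and 47.3% had the same sign. The r ranged from -0.11 without scrambled r1 to -0.03 without DMSO r2. Across all tested genes r was -0.04 on the ERCC scale and -0.10 with gene-based scaling.

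The difference was also tested by list. Of 13 genes of G1/S 11 had a more positive change with BRM014, or 12 adjusted over the list alone, with a median difference of 0.79 (camera adjusted p 1.83e-05, or 0.875 with an estimated correlation). Of 13 noncoding RNAs 7 had a more negative one, or 8 adjusted over the list alone, such as Neat1 at -2.47 ± 0.21 (median -0.78, camera adjusted p 0.000226, or 0.875 with an estimated correlation). The naive pluripotency list (median 0.48, adjusted p 0.0112), the immediate early list (0.76, adjusted p 0.0111) and the housekeeping list (0.44, adjusted p 0.004) were more positive with BRM014, each at an adjusted p of 0.875 with an estimated correlation. The Zfp list was more negative (-0.23, adjusted p 0.0394, or 0.972 with an estimated correlation). That call ended with the background subtracted (0.236) and without BRM014 r1 (0.0583), BRM014 r2 (0.0511), Chd4 shRNA r4 (0.137), DMSO r2 (0.191) or scrambled r3 (0.122).

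**Figure D4:**
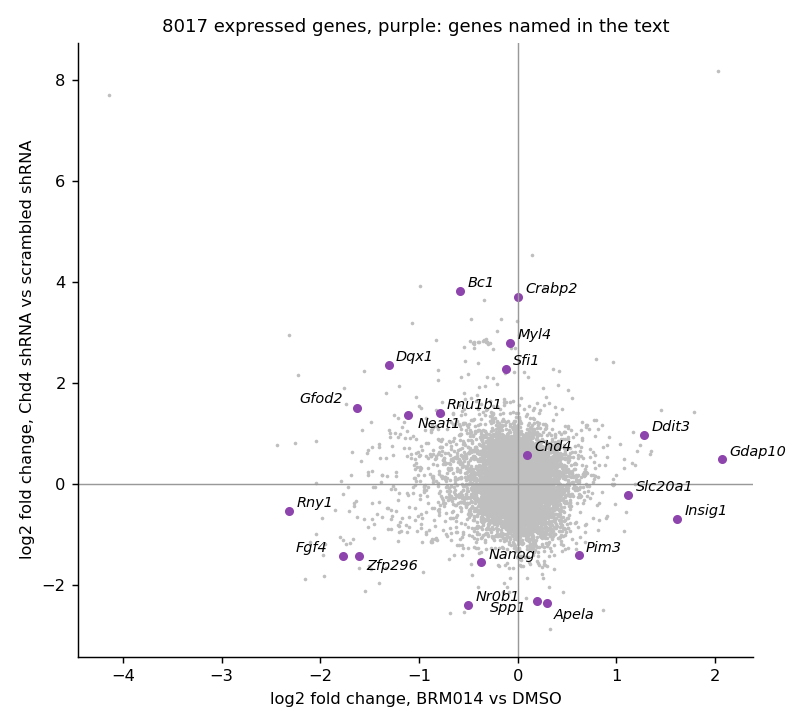
Log2 fold change in the BRM014 comparison (horizontal axis) against that in the Chd4 shRNA comparison (vertical axis) for each of 8017 expressed genes, with named genes in purple. The points form no diagonal (Pearson r -0.07), Fgf4 lies low on both axes, and Bc1 is set apart at 3.83 on the vertical axis.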

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

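Of the tests in this part, that of library size, that of a shared genome-wide source and the counts of receptor genes without the filter or with it on other libraries were chosen only after the result was seen.

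In the libraries labelled Chd4 shRNA, genes and spike-ins outside the comparisons of expressed genes gave more counts than in their controls. The 86 ERCC RNAs other than the 6 abundant ones had a mean of 48.2 CPM, relative to gene counts, against 12.03 with the scrambled shRNA. The 1434 olfactory and vomeronasal receptor genes had 6.99 counts per kb of exon against 1.58. Both values stood out as signal in data that no comparison of expressed genes uses, above the level of the controls.

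The receptor genes were weighed further. Of 1299 receptor genes with at least 20 counts in the libraries compared, which came mostly from those labelled Chd4 shRNA, 1299 were higher in the libraries labelled Chd4 shRNA, with a median log2 ratio of 2.17. Without that filter 1432 of 1434 were higher, and with it set on the BRM014 and DMSO libraries alone 966 of 966 were. A smaller library cannot produce this, since the raw counts per kb were 4.43-fold those of the scrambled libraries although the total counts were lower. Selective activation of some receptor genes was argued against too: the spread of their log2 ratios was 1.06 times that of counting noise, and 5 other gene families silent in stem cells (Tas2r, Defb, Krtap, Mrgpr and Skint) lay within -0.04 to 0.39 of the receptor genes. Background reads from 1 genome-wide source, such as genomic DNA, may account for it, but could not be tested to an answer: satellite sequence gave a mean of 4.95 counts per receptor-gene count, at 4.71 and 5.19 in the libraries labelled Chd4 shRNA and 4.09 to 5.11 in the other 6, and a broad rise of transcription at silent genes after loss of Chd4, which the design names, would look alike on these genes. The minor ERCC RNAs, at 319 and 375 counts against 136 and 144 with the scrambled shRNA, do not decide between them, as the source of their reads is not known. Their rise was not weighed further. These explanations cannot be told apart here, because no value here separates them and only 2 libraries carry the label.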

How the results depend on the processing

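Of the alternatives in this part, TMM over the 6 abundant ERCC RNAs, the robust fit, the filter on TMM-scaled gene library sizes and all those on the expressed genes were chosen only after the data were seen.

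Most of the 129 gene values from the expressed set held their direction and side of the threshold under settings with gene-based scaling. They did not with the scale fixed before the data were examined. With TMM-scaled ERCC totals only 17 of 129 held both, 111 lost their call and 1 was reversed, and with plain ERCC sums 79 held both. With the background subtracted and with the replicate block none of the named values lost its call, while 1 did with the robust fit, 1 on the 4 libraries of the comparison, 4 with DESeq2, 3 with the 30-fold set, 4 with the 3-fold set, 8 with TMM of all tested genes (where 18 more were reversed), 49 with plain ERCC sums and 111 with TMM-scaled ERCC totals. Settings without 1 library gave 29 such losses and 4 reversals of uncalled values. Counts of genes depended strongly on the scaling. On the ERCC scale, TMM over the 6 abundant RNAs in place of all 92 moved the sizes of DMSO r1 and r2 from 2.36 and 1.14 to 2.12 and 1.87. What else moved the counts was not tested beyond the constructions named. A setting that left out a library left 1 in its group, which was assumed to vary like the others.

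Over all tested genes, BRM014 gave 0 higher (edgeR; 236 at an unadjusted p under 0.05) and 2 lower. The numbers were 416 and 568 with TMM of gene counts, 10 and 74 with plain ERCC sums, 9 and 6 by DESeq2 with ERCC size factors, 426 and 136 by DESeq2 with gene size factors, 274 and 440 with a replicate block and TMM of gene counts, 33 and 211 on the 4 libraries of the comparison, 4 and 31 with TMM over the 6 abundant ERCC RNAs, and 197 and 376 with the expressed genes. The lower count was 0 with at least 50 counts (fewer genes tested), 1 with a replicate block and ERCC scaling and 1 with the robust fit. Left out in turn, libraries gave 0 to 8456 higher (6 without DMSO r1, 8456 without DMSO r2) and 0 to 1036 lower (1 without BRM014 r1 or Chd4 shRNA r1, 0 without BRM014 r2, 1036 without DMSO r1, 60 without DMSO r2).

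In the Chd4 shRNA comparison 21666 were higher and 68 lower. The numbers were 11493 and 11134 with TMM of gene counts, 3065 and 10524 by DESeq2 with gene size factors, 2885 and 26 with at least 50 counts, 11322 and 10973 with a replicate block and TMM of gene counts, and 1634 and 1621 with the expressed genes. The lower count was 617 by DESeq2 with ERCC size factors and 2147 on the 4 libraries. Left out in turn, libraries gave 13247 (without Chd4 shRNA r4) to 26850 higher and 8 to 636 lower (37 without BRM014 r1 or r2, 8 without Chd4 shRNA r1, 18 without Chd4 shRNA r4, 636 without DMSO r1, 635 without DMSO r2, 16 without scrambled r1, 40 without scrambled r3). The difference between both effects was called for 12650 genes, and for 24828 with plain ERCC sums, 6809 by DESeq2 with ERCC size factors, 1634 with at least 50 counts, 21657 with TMM over the 6 abundant ERCC RNAs and 2473 with the expressed genes. It ranged from 1591 (without BRM014 r2) to 24313 (without DMSO r1), with 7486 without BRM014 r1, 6298 without Chd4 shRNA r1, 3802 without Chd4 shRNA r4, 1795 without scrambled r1 and 7779 without scrambled r3.

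Among expressed genes, BRM014 gave 197 higher and 376 lower. The numbers were 16 and 120 at an absolute log2 fold change of at least 1, 498 and 803 at 3-fold above background (more genes tested), 52 and 203 at 30-fold (fewer), 96 and 207 by DESeq2, 0 and 0 with TMM-scaled ERCC totals (edgeR) and 13 and 93 with plain ERCC sums, while TMM of all tested genes gave 412 higher. The ranges were 85 to 762 higher and 148 to 671 lower, with 85 and 235 without BRM014 r1, 91 and 148 without BRM014 r2 and 762 and 671 without DMSO r2. The Chd4 shRNA comparison gave 1634 higher and 1621 lower, and 317 and 259, 3889 and 3873, 889 and 828, 61 and 6, 2809 and 65, and 52 and 7496 at the threshold of 1, at 3-fold, at 30-fold, with TMM-scaled ERCC totals, with plain ERCC sums and with TMM of all tested genes. The ranges were 1064 (without scrambled r3) to 1923 higher, with 1079 without Chd4 shRNA r4, and 1046 (without Chd4 shRNA r1) to 1936 lower. The difference was called for 2473 genes, and for 900, 6517, 1383, 24, 1344 and 7185 in the same order of settings, with a range of 1611 (without Chd4 shRNA r1) to 2961.

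The Pearson r between both effects was -0.041 over all tested genes and stayed negative under the settings run: -0.098 with TMM of gene counts, -0.090 with plain ERCC sums, -0.0998 by DESeq2 with ERCC size factors, -0.101 by DESeq2 with gene size factors, -0.174 with at least 50 counts, -0.148 with a replicate block and ERCC scaling, -0.099 with a replicate block and TMM of gene counts, -0.092 on the 4 libraries of each comparison and -0.089 with TMM over the 6 abundant ERCC RNAs. Its range was -0.143 (without BRM014 r2) to -0.013, with -0.089 without DMSO r2. Over expressed genes it was -0.070, -0.143 at 3-fold above background, with a range of -0.113 (without scrambled r1) to -0.025 (without DMSO r2), and -0.029 without Chd4 shRNA r1 and -0.031 without scrambled r3. The log2 fold change of Chd4 (0.78) was -0.76 with TMM of gene counts, -0.90 by DESeq2 with gene size factors and -0.76 with a replicate block and TMM of gene counts, and 1.20 with plain ERCC sums, 0.51 on the 4 libraries, 1.05 with TMM over the 6 abundant ERCC RNAs and 0.59 with the expressed genes. It ranged from 0.27 to 0.93, and was called without DMSO r1 (0.78, adjusted p 0.00251) and without DMSO r2 (0.78, adjusted p 0.0025).

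Nascent output with BRM014 (-0.11) was 0.16 with the DESeq2 size factors of the ERCC RNAs, and ranged from -0.23 to 0.005. That of the libraries labelled Chd4 shRNA (0.43) was 0.0096 with TMM-scaled ERCC totals, -0.18 with the DESeq2 size factors, 1.93 as the median over genes and 0.98 without the 20 most abundant genes, and ranged from 0.12 to 0.68. Of the list tests, 54 passed over all tested genes (43 to 65 with 1 library left out) and 18 over expressed genes (15 to 22), and 0 and 0 with an estimated correlation. Scaled by all tested genes, 17 values of the Chd4 shRNA comparison turned negative: Cenpe -0.16, Cenpf -0.17, Supt6 -0.21, Aff4 -0.21, Ell -0.43, Hspa5 -0.18, Ddit3 -0.36, Herpud1 -0.40, H3f3b -0.54, Stat3 -0.64, Malat1 -0.27, Arid1a -0.45, Zfp866 -0.21, Polr2a -0.28, Lamc1 -0.95, Chd4 -0.76 and Smarca4 -0.74. The uncalled difference of Fgf4 turned to 1.07 there and to 0.052 in the 3-fold set, that of Ddit3 to -0.29 with plain ERCC sums, and the uncalled value of Pou5f1 with BRM014 to 0.075 with TMM-scaled ERCC totals. With BRM014 the uncalled values turned to -0.03 for Chd4 and -0.02 for Smarca4 without BRM014 r1, and to -0.10 and -0.083 without DMSO r1, and ranged up to 0.32 and 0.35 without DMSO r2. The BRM014 and DMSO libraries share replicate numbers. Their deviations correlated at -0.217 by number and at 0.217 matched the other way. With 2 libraries per group these values mirror each other and do not show whether the libraries were paired. The numbers were not read as pairs, and the replicate block, which covered those 4 libraries alone, served as a check. No pairs were formed in the Chd4 shRNA comparison, whose columns share only r1, so that the block bears on it only through the pooled spread. Leaving out mitochondrial genes changed nothing, as these had 0 counts. Of 4-fold changes simulated over all tested genes, 5 of 66 and 8 of 66 were recovered on the ERCC scale against 47 of 66 and 42 of 66 with gene-based scaling, which limits what a low count on the ERCC scale can show.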

Other observations

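Of the tests in this part, that of counts summed over short genes, the bootstrap interval, the split of short genes by length and position, and the sterol test in the libraries labelled Chd4 shRNA were chosen only after the result was seen. The list of sterol genes was also written after some of its members were seen.

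Insig1 was among the largest rises with BRM014, and the sterol synthesis genes Idi1 (0.83 log2) and Msmo1 (0.82) rose with it. A hypothesis that the sterol pathway rises together was tested on 19 genes of the pathway, without the 4 that led to it. Their median log2 fold change was 0.27 and the camera p was 0.000868, but 0.203 with an estimated correlation, and 1 gene, Cyp51, was called on its own (0.53, adjusted p 0.0254, but 0.167 without BRM014 r1, 0.157 without DMSO r1 and 0.0893 at 30-fold above background). In the libraries labelled Chd4 shRNA 12 of 23 sterol genes fell and 0 rose, with a median of -0.45 (edgeR; camera p 8.54e-05, unadjusted, or 0.189 with an estimated correlation). A joint response of the pathway to SWI/SNF inhibition may explain the first result, as a hypothesis found and tested on the same libraries.

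In the Chd4 shRNA comparison the log2 fold change of expressed genes went weakly with exonic length (Spearman rho 0.091 across genes, which are not independent replicates). In 4 equal bins from short to long the medians were 0.11, -0.14, -0.11 and 0.19, which is not a steady rise. The background was then subtracted in proportion to length, which takes most from long genes in the libraries labelled Chd4 shRNA. This by itself tends to lower rho. After it rho was -0.0012, so background reads could explain the trend. Differences between libraries in how long transcripts were sampled could explain it as well, since the log2 ratio between the 2 libraries of a group had a rho of -0.211 with length for the label Chd4 shRNA and 0.282 for the scrambled shRNA (largest absolute value 0.497, between the DMSO libraries). With BRM014 rho was 0.135. No biological explanation of the trend was tested.

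Short noncoding RNAs were counted less with BRM014. Of 49 small nuclear RNA genes 39 were lower and 1 higher (median -1.12), of 142 small nucleolar RNA genes 55 were lower and 1 higher (median -0.55), and of 62 microRNA genes 17 were lower (median -0.28), against 166 lower and 5 higher of all 550 expressed genes of at most 200 bases. A loss of short fragments in the library preparation may explain it; the pseudogene class (38 genes, median 0.016) goes against that, but its 95% bootstrap interval was -0.17 to 0.15 and only 320 of the 550 genes had a class, which leaves the check void. Genes of at most 100 bases had a median of -0.12 against -0.57 for the others of the 550, but outside other genes of the same strand -0.29 (38 genes) against -0.46 (177 genes), with overlapping quartiles. Reads shared between copies also stay open, at a log2 ratio of -0.12 for counts summed over 6789 genes of at most 200 bases, and neither can be told apart from an untested effect of SWI/SNF inhibition on these genes.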
